A study of Mus musculus with 4 samples.

How the data were processed

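Gene expression was measured in 4 cultures of mouse RAW264 macrophages, 1 in each group of siRNA (GFP or Tfe3/Tfeb) and iron (none or 500 µM ferric chloride for 24 hours, begun 48 hours after transfection). Per the labels, total RNA was labelled with the dye Cy3 and hybridised to Agilent SurePrint G3 mouse arrays. Per the submitters' processing notes and the file headers, the arrays were read with Agilent Feature Extraction 12.0.3.1. The deposited scanner files give for each spot a processed intensity, which per the file headers is background-subtracted and detrended within the array and is not scaled between arrays, with flags for saturation, outliers and signal well above background. The authors' deposited series matrix holds log2 values of the same arrays. Set against the scanner values, its differences between arrays had a slope of 1.0 and a Pearson r of 1.0 in each comparison, and each of its 56602 probes had a median of 0 over the 4 arrays within 1e-05. Scale, centring and direction are therefore settled from the values: log2, each probe centred on its median over the arrays. The column medians were -0.0042, 0.022, -0.087 and 0.0013 in the order siGFP, siGFP with iron, siTfe3/Tfeb, siTfe3/Tfeb with iron. All 4 arrays lay on 1 slide and were scanned in 1 run, so no slide or scan batch separated them.

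Values were taken as log2 of the processed signal minus the 75th percentile of the non-control spots of the array. Spots flagged as outliers were left out, which removed 3 probes, and spots of 1 probe were averaged. Probes were named through a RefSeq gene table (assembly GRCm38.p6, used for names only): 33767 of 56605 probes by accession, 9866 by symbol, and 12972 named no gene. Of 24788 genes on the arrays, a gene with several probes was represented by the brightest, by its mean over the 4 arrays. Other probes of genes that differed 2-fold had the same sign for 93.2% of such probes with iron in siGFP cells and 97.1% with iron in siTfe3/Tfeb cells. With knockdown the share was 88.5% without iron and 86.8% with iron. None differed 2-fold the other way. In the same order, only 39 of 73, 58 of 104, 76 of 182 and 33 of 91 were also 2-fold the same way. Such probes were available for 59 of 237, 82 of 292, 135 of 460 and 75 of 303 of the genes. A gene not well above background on 1 of the 2 arrays has only a bound, its fold against the lowest signal well above background on that array or its own signal there, whichever was higher, and is written as at least N-fold. Genes below background on both arrays gave no value. Genes were counted as higher or lower from a 2-fold difference, and the difference of iron responses was taken for genes well above background on all 4 arrays.

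Groups of 1 array allow no test between conditions. A fit that takes the difference of iron responses as its error was not used, since that difference is itself a comparison of the design. Error was taken from 300 probes spotted 10 times and 10 spike-in probes spotted 35 times per array. Their spread gave the SD of a log2 difference by signal level, and 8 of 69904 pairs of such spots differed 2-fold. Most were bright: of 1165 combinations of probe and array, 1090 lay above a log2 level of 2. Below -4 there were 10, and from -2 to -1 there was 1. Genes that differed 2-fold had median levels from -1.54 to -3.17. The SDs of dim genes and the counts given for spot noise are therefore rough. Each gene list, of 31 fixed before the data were examined, was summarised by the median log2 difference of its measured members, with the percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, where at least 3 members were measured. Of the 689 list genes on the arrays, 24 stood in more than 1 list.

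Named genes follow a rule fixed at the same time as the lists: Tfe3, Tfeb, Mitf and Tfec; the 12 largest differences in each direction among genes well above background on all arrays of the comparison, leaving out identifier-only names and genes with another probe of opposite sign; up to 4 members of each list with the largest difference; and up to 5 of the largest bounds in each direction. A gene named for 1 comparison may be given in others.

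The procedure was tested on simulated data for the comparison of iron in siGFP cells, with 13825 genes at their measured levels, spot noise and 200 changed genes. All simulated genes counted as well above background, so the background filter and the bounds were not tested. Variation between cultures was not simulated. Of 50 genes changed by 2.5-fold, 96.0% were called 2-fold in the right direction, all 50 were at 4-fold and at 8-fold, and none at 1.5-fold. Of 13625 unchanged genes 0.25% were called. Of 200 random lists of 25 genes, 4.5% fell outside the central 95% range, and all 20 lists shifted by 0.3 lay above it.

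Alternatives were quantile normalization, median centring, normexp background correction (offset 50) with the 75th percentile or with quantile normalization, the authors' series matrix values, only genes well above background on all arrays of the comparison, no filter on background, the mean over all probes of a gene, outlier-flagged spots kept, and thresholds of 1.5-fold and 4-fold. R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Probes that name no gene stayed out of the comparisons and are given at the end.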

Results

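RAW264 is a macrophage-like cell line from a BALB/c mouse. The cells received small interfering RNA (siRNA) against the transcripts of Tfe3 and Tfeb, or against green fluorescent protein (GFP), which mouse cells do not carry, as the control. Tfe3 and Tfeb are related transcription factors of the MiT/TFE family that activate genes of lysosomes and autophagy. After 48 hours the cultures were kept with or without 500 µM ferric chloride for 24 hours, and total RNA was hybridised to 1-colour expression arrays. The 4 groups (siGFP, siGFP with iron, siTfe3/Tfeb, siTfe3/Tfeb with iron) held 1 array each. Each difference below is therefore a difference between 2 arrays with no replicate check, and no test, standard error or p-value was computed between groups.

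The arrays carried 62976 spots, of which 59305 were not controls, for 56605 probes. The 75th percentile of the processed signal was 619 in siGFP, 627 in siGFP with iron, 636 in siTfe3/Tfeb and 593 in siTfe3/Tfeb with iron, and no spot was saturated. Of 24788 named genes, 14681, 14635, 14863 and 14297 had a probe well above background on these arrays in the same order, and 13825 on all 4. The only measure of error was the agreement of repeated spots of 1 probe on 1 array. The SD of a log2 difference that this spread gives was 0.067 for bright probes, 0.12 just below the scaling level and 0.49 for the dimmest. The 0.12 and the 0.49 rest on 9 and 10 combinations of probe and array, against 1090 for the 0.067. This SD covers spotting and scanning, and leaves out variation between cultures, extractions and labellings. The number of arrays limits the precision of everything that follows.

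Most macrophage genes were detected on every array, as were some marker genes of other cell types. Of 24 macrophage identity genes, 23 were well above background on all 4 arrays, among them Lyz2 (lysozyme). This held for 1 of 9 fibroblast markers, 2 of 8 epithelial markers, 2 of 8 endothelial markers and 5 of 10 lymphocyte markers, among them Cd4.

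Tfe3 signal was lower on the arrays labelled siTfe3/Tfeb, and Tfeb signal was not clearly so. The bright Tfe3 probe (chromosome X, 7352259 to 7352318, array design coordinates on mm9) read 12421 in siGFP, 11306 in siGFP with iron, 7736 in siTfe3/Tfeb and 7315 in siTfe3/Tfeb with iron. After scaling, 60.6% of the siGFP level was left without iron (log2 difference -0.72, spot SD 0.067) and 68.4% with iron (-0.55). A far dimmer Tfe3 probe (X, 7342667 to 7342726) was well above background only in siGFP without iron. The brightest of 4 Tfeb probes (chromosome 17, 47896359 to 47896418) stood at 91.0% of the siGFP level without iron and 112% with iron, differences of -0.14 and 0.16 with a spot SD of 0.12. The other Tfeb probes (17, 47929089 to 47929148, 47924977 to 47925036 and 47926621 to 47926680) gave 105%, 88.3% and 88.3% without iron and 94.5%, 95.9% and 90.7% with iron. Whether these probes lie in coding or untranslated sequence was not analysed here. Mitf, a related factor that the siRNA was not labelled to target, was at 93.7% and 96.6% by its brightest probe. Its other probes were at 105%, 96.6% and 107% without iron. Tfec, a dim family member, differed by -0.65 without iron and 0.039 with iron. Because the labels name both targets and the brightest Tfeb probe was lower without iron by little more than its spot SD and higher with iron, the term knockdown below means only the array labelled siTfe3/Tfeb against its siGFP counterpart.

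**Figure D1:**
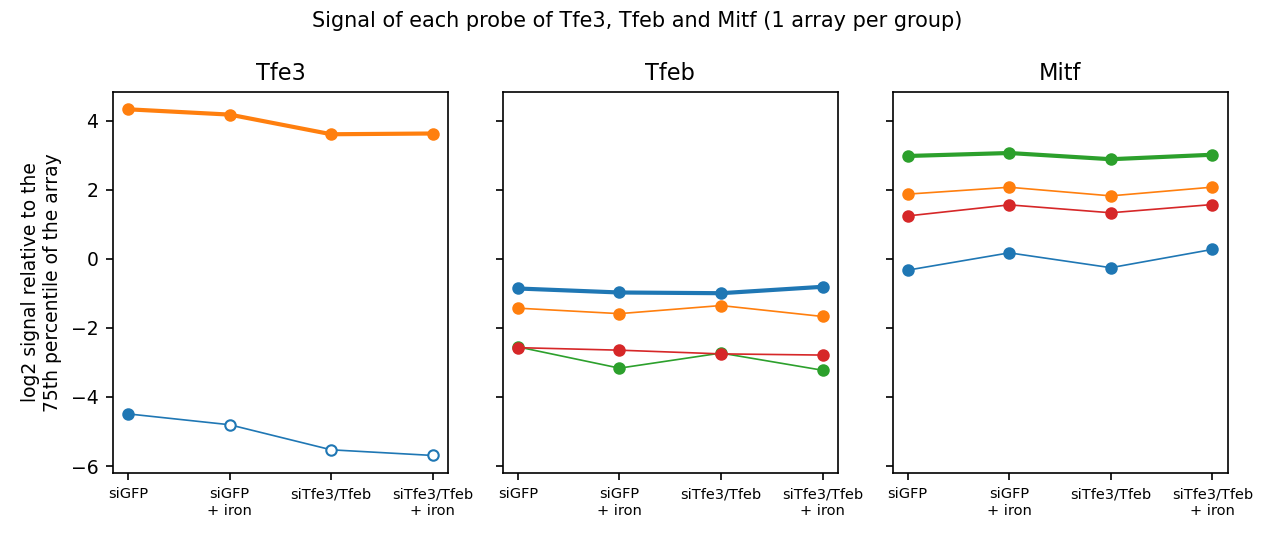
Signal of each probe of Tfe3, Tfeb and Mitf on the 4 arrays, as log2 relative to the 75th percentile of the array. Each line is 1 probe, the thick line is the probe used for the gene, and open circles are values not well above background. The bright Tfe3 probe stood at 60.6% and 68.4% of its siGFP level on the siTfe3/Tfeb arrays, while the Tfeb probes lay between 88.3% and 112%.

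With iron, genes of iron export and haem breakdown were among the largest differences in siGFP cells. Slc40a1 (ferroportin, the cellular iron exporter) was 19.0-fold higher, Hmox1 (haem oxygenase 1) 7.60-fold and Procr (the endothelial protein C receptor) 9.34-fold. Surface proteins and secreted factors were also among the largest differences: the C-type lectin Clec4n was 9.65-fold higher, Il7r (an interleukin 7 receptor chain) 7.69-fold, Pdpn (podoplanin) 7.04-fold, the growth factor Hbegf 6.98-fold and the chemokine Ccl24 5.65-fold. Tent5c (9.91-fold), Fabp4 (a fatty acid binding protein, 6.32-fold), Pgm5 (6.16-fold) and the creatine transporter Slc6a8 (6.15-fold) completed the 12 largest. Lower with iron were the formyl peptide receptor Fpr2 (5.79-fold), Mchr1 (3.76-fold), Tmem176a and Tmem176b (3.32-fold and 2.73-fold), the acute phase genes Saa3 (3.16-fold), Hp (3.15-fold) and C3 (2.95-fold), and Mmp9 (a secreted protease, 2.86-fold). Ms4a4b, Zmynd15, Frat1 and Tbx20 were lower by 2.87-fold, 2.79-fold, 2.74-fold and 2.67-fold. Genes measured on the iron array alone included Ptpn14, at least 16.7-fold higher, the chemokine Ppbp (at least 9.70-fold), Gsta2 (a glutathione transferase, at least 8.08-fold) and Hal (at least 7.01-fold). In the other direction Prl3c1, Sema6d, Phactr3, Abcd2 and Lifr were at least 2.34, 2.29, 2.27, 2.19 and 2.18-fold lower, and averaged over all probes of a gene Prl3c1, Sema6d, Phactr3 and Abcd2 had no bound left.

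In total 233 genes were at least 2-fold higher and 53 at least 2-fold lower with iron in siGFP cells. Of these, 34 and 15 were bounds, in which 1 of the arrays was not well above background. Without the bounds 199 were higher and 38 lower, where spot noise alone would give 27.2 in both directions together. With normexp background correction the counts were 126 and 20.

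By function, lists for antioxidant defence, lysosomal acidification and cholesterol synthesis were higher with iron and interferon response genes lower. The median of each is given in log2 with its place among 10000 random lists of the same size and expression level, as a description of these arrays. All 28 measured Nrf2 antioxidant targets lay above 0, with a median of 0.42, above all 10000 random lists. Of these, 9 were at least 2-fold higher, among them Gstm1 (2.08) and Gclm (1.68), which acts in glutathione synthesis. Of 18 vacuolar ATPase subunits, which acidify lysosomes, 17 were above 0 (median 0.48, above all random lists), with Atp6v0d2 at 2.34 and Atp6v0a1 at 0.88. Lysosomal hydrolases (35 of 45 above 0, median 0.23) and lysosomal membrane proteins (22 of 27 above 0, median 0.18) also lay above all random lists, with none of them 2-fold higher. Cathepsins differed in sign: Ctsd and Ctsl were at 0.97 and 0.88 and Ctsf at -0.93. MiT/TFE targets outside the lysosome had a median of 0.38, led by Gpnmb (1.42), the autophagy receptor Sqstm1 (1.13) and Fnip2 (1.09). Osteoclast genes had a median of 0.45, with Itgb3 at 1.78, Ocstamp at 1.61 and Mmp9 at -1.52. Averaged over all probes of a gene, that median was 0.16.

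Iron handling genes split. The list's median was 0.14 (percentile 99.9), with 14 of 25 members above 0, and 0.044 with no filter on background. Besides Slc40a1 and Hmox1, Blvrb (biliverdin reductase B, 1.55) and the metal transporter Slc11a1 (1.42) were higher, and Tfrc (the transferrin receptor) was at -0.89. The metallothioneins Mt2 and Mt1 stood at 1.49 and 0.70. Cholesterol synthesis genes were higher in 22 of 23 cases (median 0.43, above all random lists), with Insig1 at 0.92, and none reached 2-fold. Type I interferon response genes went the other way: 35 of 36 were below 0, with a median of -0.39, below all random lists, and Mx1 at -1.12. All 25 mitotic genes were below 0 (median -0.18). The NF-kB inflammatory list had a median of -0.042 (percentile 30.8), with members on both sides: the chemokines Ccl7, Ccl2, Ccl4 and Ccl3 stood at 2.14, 2.13, 2.10 and 1.99.

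In siTfe3/Tfeb cells genes of iron export and haem breakdown were again among the largest differences with iron. Slc40a1 was 23.2-fold higher, Clec4n 20.1-fold, Hmox1 10.9-fold, Procr 10.4-fold, Fabp4 6.96-fold and Il7r 6.33-fold. The receptor Treml4 (8.77-fold), the AP-1 subunit Fosl1 (8.01-fold), Hal (7.28-fold), Afp (6.57-fold), Atp6v0d2 (6.44-fold) and Rnf183 (6.12-fold) also stood among the 12 largest. Lower with iron were Cox6a2 (a cytochrome oxidase subunit, 3.54-fold), Lifr (3.49-fold), Fam166b (3.38-fold), Rdm1 (3.18-fold), Plxdc2 (log2 difference -1.58), Ms4a4b (2.72-fold), Ypel1 (2.68-fold), the proline synthesis gene Pycr1 (2.61-fold), Zmynd15 (2.52-fold), Aldh1l2 (2.51-fold), Matn4 (2.48-fold) and Klhl33 (2.47-fold). The largest bounds were Ptpn14, at least 19.3-fold higher, followed by Tmod1 (at least 6.06-fold), Pik3c2g (at least 5.67-fold), Serpini1 (at least 5.37-fold) and Lce1k (at least 4.51-fold). Fn3k was at least 4.26-fold lower, and Rnf122, Cracdl, Sema6d and Olfr433 at least 3.08, 2.82, 2.77 and 2.60-fold lower, where averaging over all probes left Fn3k and Sema6d no bound.

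There were 268 genes at least 2-fold higher and 105 at least 2-fold lower with iron in siTfe3/Tfeb cells, of which 40 and 41 were bounds. Without the bounds 228 were higher and 64 lower, against 28.4 in total from spot noise alone. The split was more one-sided with normexp background correction (153 higher, 17 lower) and with quantile normalization added (150 and 19). Among genes well above background on both arrays, 64 were lower.

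Nrf2 targets again lay above 0, all 27 measured, with a median of 0.83 and with Gclm at 2.28 and Gstm1 at 1.83. Nqo1 (a quinone reductase) was well above background only with iron and Gsta3 only without it, so these list members had bounds and stood outside the median. Cholesterol synthesis genes were above 0 in 23 of 23 cases (median 0.74), with Hsd17b7 at 1.19. Endoplasmic reticulum chaperones had a median of 0.43, against 0.090 in siGFP cells. The NF-kB list had a median of 0.57 in these cells, above all random lists, with 17 of 24 members above 0, among them Ccl4 (2.44), Ccl2 (2.12) and Ptgs2 (1.85). With no filter on background that median was 0.16. Osteoclast genes (0.46, or 0.28 with normexp background correction and quantile normalization) and vacuolar ATPase subunits (0.31, 17 of 18 above 0) were above all random lists, lysosomal hydrolases had a median of 0.11 (percentile 99.0, 35 of 45 above 0) and lysosomal membrane proteins were evenly divided, with 13 of 27 above 0. Non-lysosomal MiT/TFE targets had a median of 0.24, with Sqstm1 at 1.07 and Gpnmb at 0.97. Mitotic genes were all below 0 (25 of 25, median -0.45). Targets of Atf4, the transcription factor of the integrated stress response, had a median of -0.35, below all random lists, with Pck2 at -1.14 and Asns at -0.80, while Slc7a11, a member of the same list, was at 1.63. Interferon response genes had a median of -0.032 (percentile 21.7), which was 0.023 with median centring.

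**Figure D2:**
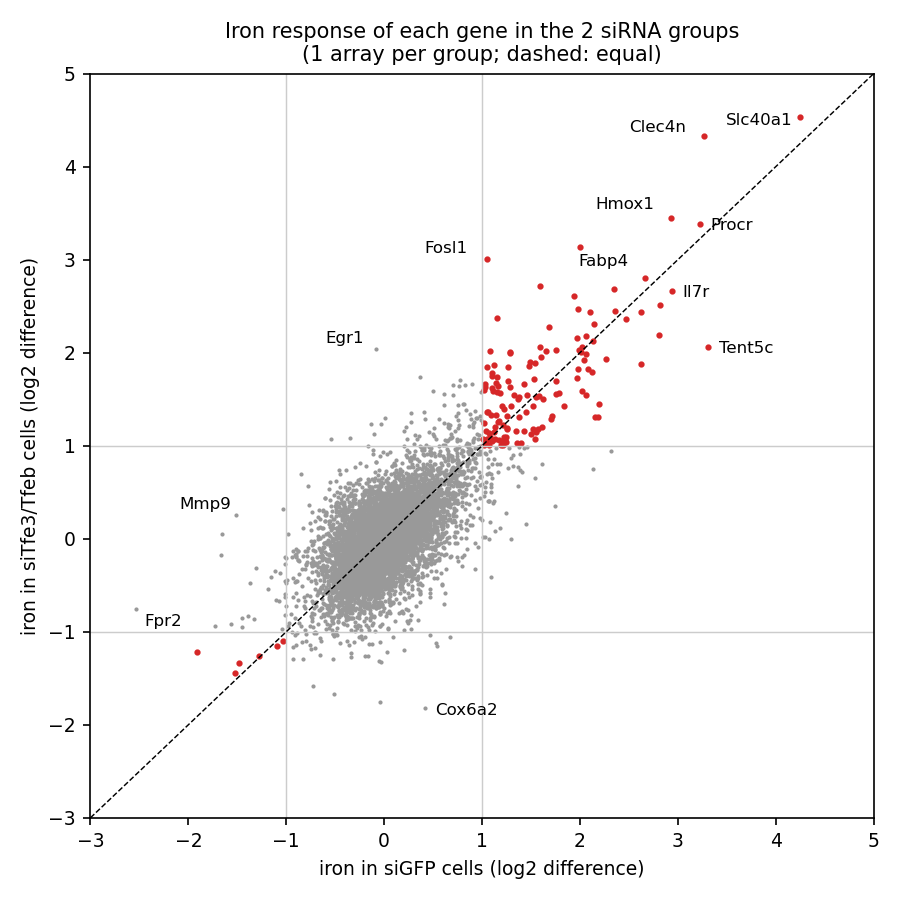
Iron response (log2 difference) of each gene well above background on all 4 arrays, in siGFP cells (x axis) and siTfe3/Tfeb cells (y axis), 1 array per group. Red points are the 130 genes at least 2-fold higher and the 6 at least 2-fold lower in both. The dashed line marks equal responses, and Pearson's r across the 13825 genes was 0.68.

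The iron responses of the siRNA groups, which share no array, were correlated across genes well above background on all 4 arrays. Of 13825 genes well above background on all 4 arrays, 185 were at least 2-fold higher in siGFP cells and 217 in siTfe3/Tfeb cells, 130 of them in both, against 2.90 for independent lists. Of 34 and 59 lower genes, 6 were in both (0.145 for independent lists), and no gene was 2-fold changed in opposite directions. Across genes, which are not independent replicates, Pearson's r was 0.68 and Spearman's rho 0.57. The 185 genes chosen in siGFP cells had a median response of 1.30 there and 1.31 in siTfe3/Tfeb cells. The 217 chosen in siTfe3/Tfeb cells had medians of 1.33 there and 1.10 in siGFP cells. With no filter on background, r was 0.22 and the median in siTfe3/Tfeb cells of higher genes chosen in siGFP cells 0.17. Of lower genes, the 34 chosen in siGFP cells had a median of -1.17 there and -0.66 in siTfe3/Tfeb cells, and the 59 chosen in siTfe3/Tfeb cells had -1.13 there and -0.52 in siGFP cells.

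Of genes with the higher iron response in siTfe3/Tfeb cells, Egr1, an immediate early transcription factor, differed most. It stood at -0.09 in siGFP cells and 2.04 in siTfe3/Tfeb cells (difference 2.13). Fosl1 (1.95), Fpr2 (1.77), Mmp9 (1.77), Hp (1.70), Olfr1500 (1.61), Eda2r (1.55), Saa3 (1.49), Cdkl4 (1.42), Cldn14 (1.37), Itga8 (1.37) and Lrrc3 (1.36) also had the higher response in siTfe3/Tfeb cells. A higher response can be a smaller or absent fall. In siGFP and siTfe3/Tfeb cells Fpr2 stood at -2.53 and -0.76, Mmp9 at -1.52 and 0.25, Hp at -1.65 and 0.046, and Saa3 at -1.66 and -0.17. The lower response there was largest in size for Cox6a2 (-2.24), then Cth (cystathionine gamma-lyase, -1.73), Fam166b (-1.71), Siglecf (-1.69), Erfe (-1.66), Adgre5 (-1.51), Serpinb1c (-1.50), Soat2 (-1.40), Ccl7 (-1.39), Lrrc32 (-1.39), Lta (-1.32) and Vwf (-1.30). The difference of responses was 2-fold or more for 39 genes in the higher direction and 48 in the lower. Spot noise alone would give 92.6, so these counts were not above the spot error. Single genes varied in this. The spot SD of the difference was 0.13 for Saa3, 0.16 for Adgre5, 0.17 for Egr1 and 0.24 for Cox6a2. For the dim Lta, Cldn14, Eda2r and Serpinb1c it was 0.50, 0.56, 0.57 and 0.63. The share of higher genes, 44.8%, was 57.5% with quantile normalization, 63.2% with median centring and 57.9% with normexp background correction. With normexp background correction and quantile normalization it was 47.6%, and with the series matrix values 48.8%.

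As lists, Atf4 targets (-0.34) and mitotic genes (-0.27) had the lower response in siTfe3/Tfeb cells, each below all random lists. Interferon response genes (0.30, 34 of 35 above 0), NF-kB genes (0.29), cholesterol synthesis genes (0.27), endoplasmic reticulum chaperones (0.27), p53 targets (0.26) and Nrf2 targets (0.22) had the higher response, each above all random lists. With normexp background correction and quantile normalization the NF-kB median was 0.16 and the Nrf2 median 0.11. For each gene the difference of responses is also the knockdown difference with iron minus that without iron. The knockdown medians without iron had the opposite sign for each list above. They were 0.72 (Atf4), 0.37 (mitotic), -0.58 (interferon), -0.57 (NF-kB), -0.28 (cholesterol), -0.58 (chaperones), -0.16 (p53) and -0.067 (Nrf2). A deviation of 1 culture without iron can therefore not be told apart from a changed iron response. Lists of the lysosome and of other MiT/TFE targets had slightly lower responses in siTfe3/Tfeb cells: vacuolar ATPase subunits -0.11 (percentile 0.22), lysosomal membrane proteins -0.14 (0.030), non-lysosomal MiT/TFE targets -0.15 (0.10) and lysosomal hydrolases -0.069 (0.315). With median centring the hydrolase median was 0.0016. That setting added 0.071 to the difference of every gene, and so to the other lists and random lists too. Autophagy machinery stood at -0.10 (0.29).

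Without iron, the genes with the largest lower signal on the knockdown array included secreted proteases, surface proteins and a chemokine, and those with the largest higher signal included enzymes of amino acid metabolism. Itgax (the CD11c integrin chain) was 21.8-fold lower on the array labelled siTfe3/Tfeb, the secreted proteases Mmp9 and Mmp12 13.3-fold and 9.35-fold, Ccdc80 11.5-fold, Pdpn 8.40-fold, Serpinb10 8.37-fold, the growth factor Areg 8.17-fold and the chemokine Ccl2 7.15-fold. The immediate early genes Egr1, Fosl1 and Egr2 were 7.90-fold, 6.82-fold and 5.92-fold lower, and Afp 7.02-fold. Higher were Cox6a2 (13.1-fold), Aldh1l2 (a mitochondrial folate enzyme, 7.63-fold), Cth (7.01-fold), Pycr1 (6.30-fold), Glrp1 (5.13-fold), Morn1 (4.66-fold), Pck2 (mitochondrial PEP carboxykinase, 4.60-fold), Plppr3 (4.23-fold), Fn3k (3.91-fold), Rdm1 (3.80-fold), Gpt2 (an alanine aminotransferase, 3.68-fold) and the glycine transporter Slc6a9 (3.66-fold). Of genes below background on 1 side, Wdr95, Slc6a4, Tnc, Tssk6 and Cyp2s1 were at least 7.29, 7.21, 4.60, 4.36 and 4.24-fold lower, and Nrbp2, Tbx6, Rnf122 and Klhl33 at least 5.85, 4.03, 3.16 and 3.01-fold higher.

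The knockdown counts without iron were 224 genes at least 2-fold higher and 318 lower, with 25 and 57 bounds. Without the bounds 199 were higher and 261 lower, against 31.1 in total from spot noise alone. With normexp background correction the counts were 80 and 155.

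Among the lists, Atf4 targets had a median of 0.72, above all random lists, with 25 of 30 members above 0 and Trib3 and Chac1 at 1.79 and 1.76. All 35 measured interferon response genes were below 0 (median -0.58), 11 of them at least 2-fold, led by Ifit1 (-2.42), Ifit3 (-2.17) and Cxcl10 (-1.98). NF-kB genes (20 of 24 below 0, median -0.57) included Il1b at -2.22 and Tnf at -2.15, and with no filter on background had a median of -0.23. Endoplasmic reticulum chaperones (18 of 20 below 0, median -0.58) were led by Manf (-1.17) and Hspa5 (-1.08). Osteoclast genes had a median of -0.64, with Atp6v0d2 at -2.46, Acp5 at -1.37 and Ctsk at -1.21. The interferon, NF-kB, chaperone and osteoclast medians were below all random lists, as was that of 8 alternative activation genes (-0.57), where Il1rn was at -1.81 and Klf4 at 1.22. The alternative activation median was -0.35 with normexp background correction and -0.29 with no filter on background.

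The lysosomal, non-lysosomal MiT/TFE target and autophagy lists were not lower as a whole. The MiT/TFE target and autophagy lists share members, among them Sqstm1 and Wipi1, and Gdf15 is in both the MiT/TFE target and the Atf4 list. Lysosomal hydrolases had a median of 0.15 (percentile 99.98, 30 of 45 above 0), with only Acp5 and Ctsk at least 2-fold lower. Lysosomal membrane proteins stood at 0.11 (97.47), vacuolar ATPase subunits at -0.048 (48.7; 0.0043 with quantile normalization), non-lysosomal MiT/TFE targets at 0.19 (99.2) and autophagy machinery at 0.27, above all random lists, with Wipi1 at 1.20. Averaged over all probes of a gene, lysosomal membrane proteins had a median of 0.28 and vacuolar ATPase subunits 0.053. Of the vacuolar ATPase subunits, Atp6v0d2 alone was 2-fold lower.

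Cell cycle and metabolism lists moved in both directions, and the iron handling median was inside the random range at 0.097 (percentile 93.9), with Tfrc at -1.29 and Slc39a14 at -0.73. DNA replication genes were below 0 in 27 of 28 cases (-0.38, Mcm4 at -0.78) while mitotic genes were above 0 in 24 of 25 (0.37, Nusap1 at 0.84). Cholesterol synthesis genes had a median of -0.28 (0.12), with Hsd17b7 at -1.07. Glycolysis and hypoxia genes stood at 0.30, above all random lists, with Adm at 1.52 and Vegfa at 1.08. The 24 macrophage identity genes had a median of -0.26 (0.11), with Cd36 (a scavenger receptor) at -2.02 and Clec4n at -1.86.

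With iron, knockdown again went with lower Itgax (11.4-fold), Pdpn (10.3-fold), Mmp12 (log2 difference -3.32), Ccl2 (7.20-fold), Serpinb10 (6.97-fold), Ccdc80 (6.46-fold) and Cd36 (5.74-fold). The cystatin-like genes Stfa2l1, Cstdc4 and Cstdc5, near-identical copies that probes may not tell apart, were 8.03-fold, 7.01-fold and 6.59-fold lower, and Slc6a4 and Ccl6 5.40-fold and 5.37-fold. Higher were the adhesion receptor Adgrg1 (4.53-fold), Gnal (3.94-fold), Fam71f2 (3.94-fold), Cdkl4 (3.47-fold), Myadml2 (3.35-fold), Gipr (3.22-fold), Dixdc1 (3.18-fold), Aldh1l2 (3.11-fold), Mirt1 (log2 difference 1.63), Klhl24 (2.92-fold) and the near-identical Selenbp2 and Selenbp1 (3.23-fold and 3.07-fold). Genes measured on 1 side only were led by Ccl24, at least 13.0-fold lower, Ppbp (at least 9.46-fold lower), Gsta2 (at least 7.88-fold lower), Cracdl (at least 5.80-fold lower) and Prkg2 (at least 5.73-fold lower). Pik3c2g, Pycr1, Nrbp2, Lce1k and Abcd2 were at least 5.69, 4.95, 4.71, 4.08 and 3.74-fold higher, the last with no bound left when averaged over all probes.

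In this comparison 144 genes were at least 2-fold higher and 262 lower, with 27 and 76 bounds. Without the bounds 117 were higher and 186 lower, against 24.2 in total from spot noise alone. The share of higher genes, 35.5%, was 48.4% with median centring (195 higher, 208 lower). With normexp background correction the counts were 52 and 96.

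The list medians with iron kept the sign they had without it for Atf4 targets (0.38, 28 of 31 above 0, Gdf15 at 1.44), interferon response (-0.36, 32 of 36 below 0, Ifit1 at -1.49), osteoclast genes (-0.55), endoplasmic reticulum chaperones (-0.31), glycolysis and hypoxia (0.32, Bnip3 at 1.23) and autophagy machinery (0.23), all outside all 10000 random lists. NF-kB genes (-0.28, percentile 0.030), DNA replication (-0.26, 0.040), mitotic genes (0.15, 99.8) and alternative activation (-0.34, 1.27) also did. With median centring the NF-kB, DNA replication and mitotic medians were -0.19, -0.17 and 0.25, and averaged over all probes of a gene the alternative activation median was -0.22. Vacuolar ATPase subunits stood at -0.15 (4.99) with 14 of 18 below 0, lysosomal hydrolases at 0.062 (98.0) and lysosomal membrane proteins at 0.016 (77.6). With median centring these medians were -0.059, 0.16 and 0.11. Nrf2 targets stood at 0.16 (99.9; 0.26 with median centring) and ferroptosis genes at 0.22 (99.99).

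**Figure D3:**
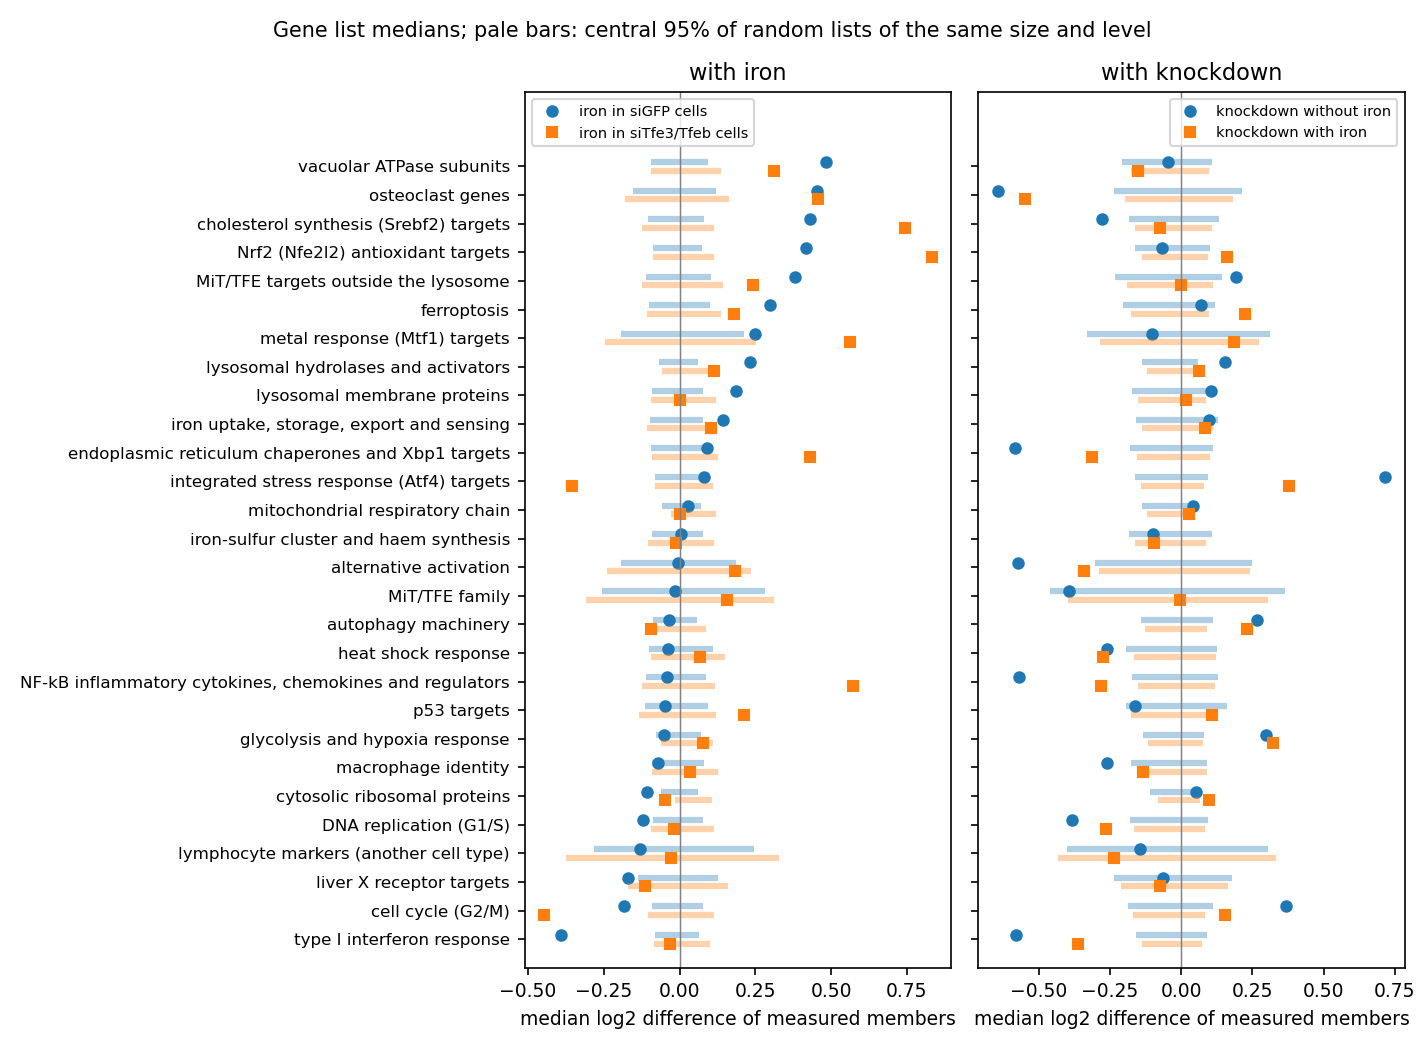
Median log2 difference of the measured members of each gene list (points) with the central 95% of random lists of the same size and expression level (pale bars), for iron in each siRNA group (left) and for knockdown without and with iron (right). Lists with at least 3 measured members in each comparison are drawn. Vacuolar ATPase, Nrf2 and cholesterol synthesis medians were above the bars with iron in both siRNA groups, and Atf4 targets above and interferon genes below the bars with knockdown.

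The knockdown comparisons, which share no array with each other, overlapped in both directions. Of 189 and 113 higher genes 74 were in both (1.54 for independent lists), and of 251 and 173 lower genes 122 were in both (3.14). Across genes Pearson's r was 0.78 and Spearman's rho 0.73, and no gene was 2-fold changed in opposite directions.

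**Figure D4:**
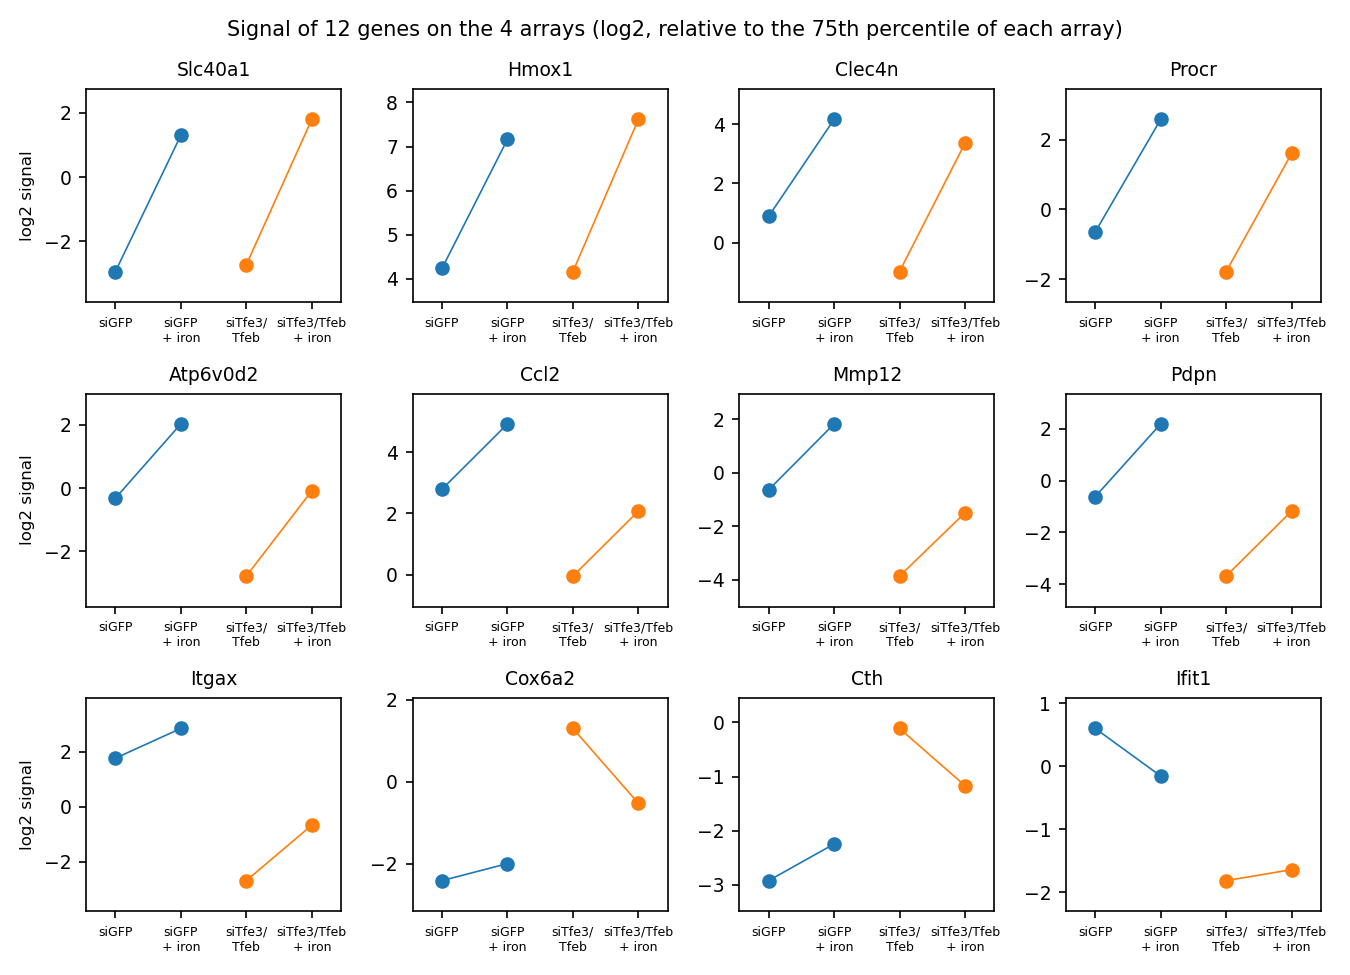
Signal of 12 genes on the 4 arrays, as log2 relative to the 75th percentile of each array, with blue for siGFP and orange for siTfe3/Tfeb and a line joining the arrays without and with iron. Each point is 1 array. Slc40a1 and Hmox1 were higher with iron at similar levels in both siRNA groups, Itgax, Pdpn and Mmp12 were lower on both siTfe3/Tfeb arrays, and Cox6a2 and Cth were highest in siTfe3/Tfeb without iron.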

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

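All tests in this part were chosen after the results were seen. The list and genes below had effects of opposite sign in the siRNA groups or in the iron conditions. None of these differences was tested, since each value comes from 1 pair of arrays, and the genes were picked for their large differences.

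The Atf4 target list moved in opposite directions with iron, at 0.082 in siGFP cells and -0.35 in siTfe3/Tfeb cells, and was higher on the siTfe3/Tfeb array without iron (median 0.72). The lowest list median for knockdown without iron over the 5 other scalings was 0.70, above the random range. These scalings shifted the median of all genes by only -0.017 to 0.024 in that comparison. The check could therefore hardly have come out otherwise and does not decide on scaling as a cause. A single deviating culture without iron, as the whole cause of the knockdown difference, would leave no difference in the pair with iron. That pair uses neither array, and the median there was 0.38. The opposite iron responses are not covered by this check. The -0.35 and the 0.72 both use the siTfe3/Tfeb array without iron, so a deviation of that culture remains possible for them. An effect of the siRNA beyond its targets cannot be told apart from an effect of losing Tfe3, because 1 siRNA treatment against the targets was compared, and both stay open.

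Several single genes responded to iron in opposite directions. Cth stood at 0.68 in siGFP cells and -1.06 in siTfe3/Tfeb cells, Siglecf at 0.54 and -1.15, Adgre5 at 0.47 and -1.04, and Olfr1500, an olfactory receptor gene, at -0.55 and 1.07. With knockdown, Hp stood at -0.64 without iron and 1.06 with iron, and Olfr1500 at -1.16 and 0.45.

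Probes that name no gene also responded to iron. Of 4879 well above background on all 4 arrays, 51 were at least 2-fold higher in siGFP cells and 40 in siTfe3/Tfeb cells, and 23 were higher in both, against 0.418 for independent lists. Their genes were not analysed here.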

How the results depend on the processing

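The alternatives in this part were planned with the gene lists, while the tally of leading differences and bounds that stayed at least 2-fold, the extension of the alternatives from the leading genes to all named genes, and the counting of a bound that fell to 0 as moved were chosen after the results were seen. Each alternative changed 1 choice at a time, or background and scaling together where both are named. No alternative left out a replicate and no paired analysis was run, because each group had 1 array. A change of sign was counted as a reversal only for list medians outside the central 95% of random lists, for genes that differed by at least 2 spot SDs and for the summaries of the iron responses; smaller values that changed sign count as moved or, within the spread, as the same. By this rule no target value or summary of the iron responses reversed, and 68 of 177 values, counts included, moved by more than their spread, or by more than 1.5 times for counts. Tfeb with iron, which was within 2 spot SDs of 0, changed sign. Of 1269 list medians 94 moved and 5 reversed, and of 6179 values of named genes 900 moved and 17 reversed. The authors' series matrix values and keeping outlier-flagged spots moved none of these. The 28 list medians that moved with median centring were all for knockdown with iron. There median centring added 0.095 to the difference of every gene, and so to random lists too. Unless said otherwise the cause of a change was not tested.

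Of the 120 leading differences named, all stayed at least 2-fold with quantile normalization, median centring, the series matrix values, no filter on background and only genes above background on all arrays. There were 95 with normexp background correction, 96 with quantile normalization added, and 109 with the mean over all probes. Of 40 bounds named, 21, 18 and 19 stayed at least 2-fold in the same order.

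The counts of higher and lower genes depended on the treatment of dim probes. Under normexp background correction, which raises dim signals and so makes differences smaller, they were 126 and 20 for iron in siGFP cells, 153 and 17 for iron in siTfe3/Tfeb cells, 80 and 155 for knockdown without iron, 52 and 96 for knockdown with iron, and 11 and 8 for the difference of iron responses. With quantile normalization added they were 128 and 20, 150 and 19, 84 and 142, 53 and 93, and 10 and 11 in the same order. With no filter on background, which adds genes near background on both arrays, they were 898 and 672, 581 and 1277, 924 and 1055, 451 and 1540, and 818 and 1698. With only genes well above background on all arrays of the comparison, 64 were lower with iron in siTfe3/Tfeb cells. The balance of the difference of iron responses, 39 higher and 48 lower, turned with quantile normalization (50 and 37) and with normexp background correction (11 and 8). It also turned with median centring (60 and 35), which added 0.071 to the difference of every gene. It did not turn with the series matrix values (42 and 44) or with normexp background correction and quantile normalization (10 and 11). The mean over all probes gave 65 higher and 114 lower.

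With a 1.5-fold threshold the counts were 709 and 339, 739 and 661, 1007 and 1266, 625 and 989, and 360 and 344. A 4-fold threshold gave 43 and 2, 44 and 2, 10 and 46, 7 and 33, and 1 and 1. The correlation of the iron responses was 0.22 with no filter on background. The median in siTfe3/Tfeb cells of genes chosen in siGFP cells as higher was 0.17 with no filter, 0.76 from a 1.5-fold and 2.10 from a 4-fold threshold, and the reverse choice gave 0.64, 0.67 and 2.02.

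Tfe3 stayed lower throughout. Without iron its difference was -0.64 with quantile normalization, -0.65 with normexp background correction and quantile normalization, and -0.88 as the mean over its probes. With iron it was -0.45 with median centring, -0.48 with normexp background correction and quantile normalization, and -0.72 as the mean over its probes. Tfeb with iron was at -0.030 as the mean over its probes, against 0.16 for the brightest.

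List medians are in log2. With quantile normalization, the medians for iron in siTfe3/Tfeb cells were 0.071 (lymphocyte markers). Those for knockdown without iron were 0.29 (non-lysosomal MiT/TFE targets), 0.47 (mitotic genes) and -0.0025 (ribosomal proteins). Those for knockdown with iron were 0.0093 (ribosomal proteins), -0.12 (lymphocyte markers) and -0.70 (osteoclast genes). Those for the difference of iron responses were 0.015 (iron handling). With median centring, the medians for iron in siTfe3/Tfeb cells were 0.0077 (ribosomal proteins). Those for knockdown with iron were -0.17 (DNA replication), 0.089 (MiT/TFE family), 0.094 (non-lysosomal MiT/TFE targets), -0.19 (NF-kB genes), 0.26 (Nrf2 targets), -0.25 (alternative activation) and 0.33 (autophagy machinery). Further ones were 0.25 (mitotic genes), 0.021 (cholesterol synthesis), 0.19 (ribosomal proteins), -0.22 (endoplasmic reticulum chaperones), 0.32 (ferroptosis), 0.42 (glycolysis and hypoxia) and -0.18 (heat shock response). Further ones were 0.47 (Atf4 targets), 0.18 (iron handling), -0.0020 (iron-sulfur cluster and haem synthesis), 0.020 (liver X receptor targets), -0.14 (lymphocyte markers), 0.16 (lysosomal hydrolases) and 0.11 (lysosomal membrane proteins). Further ones were -0.041 (macrophage identity), 0.28 (Mtf1 targets), 0.12 (respiratory chain), -0.45 (osteoclast genes), 0.20 (p53 targets), -0.27 (interferon response) and -0.059 (vacuolar ATPase). Those for the difference of iron responses were 0.0016 (lysosomal hydrolases).

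With normexp background correction, the medians for iron in siTfe3/Tfeb cells were 0.40 (NF-kB genes), 0.086 (lymphocyte markers) and 0.32 (osteoclast genes). Those for knockdown without iron were -0.22 (MiT/TFE family), -0.35 (alternative activation) and -0.19 (epithelial markers). Those for knockdown with iron were -0.025 (lymphocyte markers). With normexp background correction and quantile normalization, the medians for iron in siTfe3/Tfeb cells were 0.33 (NF-kB genes), 0.10 (alternative activation), 0.64 (cholesterol synthesis) and 0.28 (osteoclast genes). Those for knockdown without iron were -0.19 (MiT/TFE family), 0.29 (non-lysosomal MiT/TFE targets), -0.46 (NF-kB genes), -0.29 (alternative activation), 0.47 (mitotic genes), -0.0010 (ribosomal proteins) and -0.13 (epithelial markers). Those for knockdown with iron were -0.0053 (ribosomal proteins), -0.039 (lymphocyte markers) and -0.66 (osteoclast genes). Those for the difference of iron responses were 0.16 (NF-kB genes), 0.11 (Nrf2 targets) and -0.019 (osteoclast genes).

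With no filter on background, the medians for iron in siGFP cells were 0.13 (ferroptosis), 0.044 (iron handling), -0.22 (lymphocyte markers) and 0.33 (osteoclast genes). Those for iron in siTfe3/Tfeb cells were 0.16 (NF-kB genes), -0.0068 (liver X receptor targets), -0.43 (lymphocyte markers) and 0.36 (osteoclast genes). Those for knockdown without iron were -0.23 (NF-kB genes), -0.29 (alternative activation), -0.083 (epithelial markers) and -0.76 (osteoclast genes). Those for knockdown with iron were -0.010 (iron handling). Those for the difference of iron responses were 0.15 (NF-kB genes) and -0.062 (lymphocyte markers). With the mean over all probes of a gene, the medians for iron in siGFP cells were 0.48 (non-lysosomal MiT/TFE targets), 0.19 (alternative activation), -0.076 (liver X receptor targets) and 0.16 (osteoclast genes). Those for iron in siTfe3/Tfeb cells were 0.71 (Nrf2 targets), 0.65 (cholesterol synthesis), -0.24 (Atf4 targets), 0.13 (lymphocyte markers) and 0.57 (osteoclast genes). Those for knockdown without iron were -0.083 (MiT/TFE family), 0.085 (epithelial markers), 0.28 (lysosomal membrane proteins), -0.68 (interferon response) and 0.053 (vacuolar ATPase). Those for knockdown with iron were -0.15 (MiT/TFE family), -0.22 (alternative activation), -0.43 (endoplasmic reticulum chaperones), 0.43 (glycolysis and hypoxia), 0.0081 (lymphocyte markers) and -0.73 (osteoclast genes). Those for the difference of iron responses were 0.043 (MiT/TFE family) and 0.22 (osteoclast genes).

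Single genes reversed mostly with the mean over all probes. For iron in siTfe3/Tfeb cells these were Clec10a (-0.0038), Hsp90aa1 (-0.22), Dnaja1 (-0.12), Ms4a1 (0.42), Uqcrfs1 (0.0051) and Atp6v1h (-0.071). For knockdown without iron they were Dnaja1 (0.56), Hsp90aa1 (0.25), Alad (0.48), Sidt2 (-0.062) and Atp6v1h (0.14), and with iron Alad (0.21). For the difference of iron responses they were Hsp90aa1 (-0.76), Dnaja1 (-0.75) and Slc17a5 (-0.00071), and Tax1bp1 stood at 0.036 with normexp background correction and 0.0074 with quantile normalization added.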

Other observations

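The tests of explanations and the sets of genes in this part were chosen after the results were seen, while the gene lists were fixed earlier. Lists of metabolism and stress genes gave mostly small medians, some of them outside the random range, with single members that differed more. Glycolysis and hypoxia genes were little changed by iron, with medians of -0.051 in siGFP cells and 0.076 in siTfe3/Tfeb cells, although Ndrg1 was at 0.61 and 0.63. The p53 target list stood at -0.049 and 0.21 with iron (percentiles 26.8 and 99.9), led by Plk2 at 2.15 and 2.31. With knockdown the list stood at -0.16 and 0.11 (the latter 0.20 with median centring). Ferroptosis genes had medians of 0.30 (above all random lists, 0.13 with no filter on background) and 0.18 (percentile 99.5) with iron. The cystine transporter Slc7a11 was at 1.03 and 1.63. With knockdown without iron the ferroptosis median was 0.070. Targets of Mtf1, which senses metals, had medians of 0.25 and 0.56 with iron (percentiles 98.5 and 99.7). With knockdown their medians were -0.10 and 0.18 (the latter 0.28 with median centring).

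The medians of the other lists were small, and some of them lay outside the random range. Iron-sulfur cluster and haem synthesis genes had medians of 0.0053 and -0.013 with iron, both of which changed sign under other scalings, and -0.10 and -0.097 with knockdown, with Alas1, the first enzyme of haem synthesis, at 0.51 and 0.61 with iron. The respiratory chain stood at 0.028 with iron in siGFP cells and at 0.042 and 0.029 with knockdown. Ribosomal proteins had medians of -0.11 (percentile 0.010) and -0.048 with iron and of 0.051 and 0.099 with knockdown, of which the last 3 changed sign under at least 1 other scaling. Heat shock genes stood at -0.038 and 0.067 with iron and at -0.26 and -0.27 with knockdown (percentiles 0.36 and 0.080), with the chaperone gene Hspa1b below 0 in all 4 comparisons. Liver X receptor targets stood at -0.17 (percentile 0.58) and -0.11 with iron and -0.064 and -0.074 with knockdown (the last 0.020 with median centring), and macrophage identity genes at -0.073 and 0.033 with iron (the latter -0.024 with quantile normalization) and -0.14 with knockdown with iron. The MiT/TFE family itself had medians of -0.015 and 0.16 with iron, the former of opposite sign with normexp background correction, and lymphocyte markers of -0.13 and -0.029 (0.071 with quantile normalization). DNA replication genes stood at -0.12 (percentile 0.26) and -0.019 with iron (the latter 0.036 with median centring), autophagy machinery at -0.034 and -0.095, and alternative activation genes at -0.0066 (0.19 averaged over all probes of a gene) and 0.18 (0.095 with normexp background correction and quantile normalization). Liver X receptor targets had -0.076 with iron in siGFP cells when averaged over all probes and -0.0068 in siTfe3/Tfeb cells with no filter on background. With median centring the medians for knockdown with iron were -0.18 for heat shock genes, -0.041 for macrophage identity genes, 0.12 for the respiratory chain and -0.0020 for iron-sulfur cluster and haem synthesis genes.

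Some genes were measured with iron in 1 siRNA group alone. Of genes well above background on neither siTfe3/Tfeb array, 15 were at least 2-fold higher with iron in siGFP cells, and 4 at least 4-fold: Gm10639, Ppbp, Gsta2 and Gm10413. In the reverse case there were 17, and Pik3c2g, Gm8633 and Lce1k passed 4-fold. These sets were chosen after their values were seen.

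More genes were both higher with iron and lower with knockdown than independent lists would share. With the iron and the knockdown differences each averaged over their pairs of arrays, 181 of 13825 genes were at least 2-fold higher with iron and 198 at least 2-fold lower with knockdown, and 37 were both, against 2.59 for independent lists. The other combinations held 4 genes (higher in both, against 1.51), 3 (lower with iron and higher with knockdown, against 0.166) and 2 (lower in both, against 0.286). Pearson's r of the averaged differences across genes was -0.25. Both averages use the same 4 arrays. The siGFP array with iron and the siTfe3/Tfeb array without iron enter them with opposite signs. A deviation of either would by itself give a negative r, so this r is not read as a shared effect. The 37 genes included Clec4n, Procr, Fabp4, Pdpn, Atp6v0d2, Hbegf, Mmp12, Ccl2, Ccl4, Il1rn and Itgax. Chance overlap of genes drawn independently was argued against, since the highest of 10000 draws matched on expression was 12. The draws do not cover genes that move together, so an overlap from such genes was not tested. A single deviating array would leave some pairs without a difference, whereas 37 of the 37 genes differed the same way by at least 0.5 in all 4 pairs. Under the other scalings the smallest ratio to the independent overlap came with 38 genes in both, against 2.69, while normexp background correction gave 17, against 0.924, and 16 with quantile normalization added, against 0.870. No biological explanation was tested.

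Lysosomal hydrolase genes were not lower with knockdown, although Tfe3 and Tfeb are known to activate such genes. The lowest median without iron over the 5 other scalings was 0.14. These scalings shifted the median of all genes by only -0.017 to 0.024, too little to put the list below the random range. This check therefore does not decide on scaling as a cause. Higher Mitf transcript, as a replacement, was not clearly seen. The brightest Mitf probe differed by -0.094 without iron, and the others by 0.071, -0.051 and 0.091. Incomplete knockdown may account for the lack of a fall: 60.6% of the Tfe3 signal was left and Tfeb transcript was not clearly lower. By itself it would not give a median above the random range, as was seen without iron (0.15, percentile 99.98). The 60.6% was known before this explanation was weighed, so it is no test of it. Protein levels were not analysed here.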
